A study of Mus musculus with 2 samples.

How the data were processed

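Polyadenylated RNA of MEL cells, a mouse erythroleukemia line, was sequenced single-end in 2 libraries that the labels call biological replicates 1 and 2 of 1 group. Per the file headers and the text file that accompanies each sample, reads were aligned to the mm10 genome and to its transcriptome and quantified per gene and per transcript with the GENCODE M4 annotation. The aligner, the quantifier and the use of strand are not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. The deposited expected counts are estimated reads per gene or transcript, with reads that map to several places divided by a model. Deposited TPM values were scaled by the authors by effective length and to a fixed sum per library, and deposited FPKM values by effective length and the number of fragments. The deposited score columns, which hold the bounds of a credibility interval of TPM and the posterior SD of the count, describe the uncertainty of assigning reads within 1 library. No step of read processing was repeated.

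Replicate 1 held 67735380 and replicate 2 held 79923143 expected counts on 43346 genes. The files also list 97 spike-in sequences, all at 0, and 26248 short features with numeric identifiers (median length 73 nt), which took 0.0574% and 0.131% of expected counts and 2.93% and 6.24% of TPM. Both kinds were left out of library sizes and tests, and TPM was not rescaled. Symbols, types and positions came from GENCODE M21 on the same build, matched by identifier without version. This gave symbols to 42462 genes, while 884 had none (0.257% and 0.248% of counts). Of 103639 transcripts, 101510 matched, 57625 of them with the same version, so some named transcripts differ in detail between annotation releases. GC content was known for 15161 of 15251 tested genes (99.4%).

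The 31 gene lists, 40 gene pairs and 40 genes for transcript shares were chosen before the data were examined. Listed names Hbb-b1, Hbb-b2, Ahsp, Rhce, Rpl40, Rn7sl1, Rn45s, Snhg1, Snhg8 and Lincred1 had no match and were not used here, and Tcfcp2, Setd8 and Rn18s-rs5 were matched by synonym to Tfcp2, Kmt5a and Gm42418. Genes named in the text are the 20 protein-coding genes with the highest mean TPM; of each list up to 6 highest and 4 lowest members; all globins, heme enzymes, Friend loci and X inactivation and Y-linked genes; both genes of each pair; the genes chosen for transcript shares; and of the genes differing between replicates the 15 with the largest excess in each replicate among those with a summed count of at least 200, gene models without an assigned symbol left out. The X-linked homologs of the Y-linked genes lie outside this rule and were named with their test before their values were computed. Values of some single listed genes are not reported here.

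A gene was called detected at TPM of at least 1 in both replicates. For each list, the median of the mean TPM was placed among 10000 random lists of protein-coding genes of the same size. The list of erythroid surface, skeleton and cytosol genes was compared with 7 lists of other lineages by a two-sided permutation test of mean log2(TPM + 1) with 100000 permutations and Benjamini-Hochberg adjustment. Pairs were compared by the log2 ratio of TPM with a pseudocount of 0.1. Between replicates, rounded expected counts of genes with a summed count of at least 20 were compared by a two-sided exact conditional binomial test with library sizes scaled by TMM in edgeR 4.0.16. Genes were counted at an adjusted p under 0.05 and a difference of at least 2-fold. The biological coefficient of variation came from edgeR with an intercept only. For each list with at least 3 tested members, the median log2 ratio (prior count 0.5) was placed among 10000 random lists matched on expression in 20 bins. The GC trend was a lowess curve with a fraction of 0.3. A gene was said to share reads with near-identical copies when its posterior SD exceeded 3 times the counting error. Software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

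The alternatives were other TPM and count minimums, FPKM, posterior mean TPM, other pseudocounts, DESeq2 size factors, library totals, edgeR's exact test, protein-coding genes alone, random lists from expressed genes, shares of expected counts, and each replicate left out in turn. Added after the data were examined were removal of the GC trend, of the length trend, of the GC trend within 4 classes of expression and of GC, length and expression trends together, and the leaving out of genes that share reads. The steps were tested on simulated data. For the comparison of the replicates over 15251 genes, the binomial test called 87 of 100 genes changed 3-fold, 93 of 100 changed 5-fold and 0 of 15051 unchanged. With a GC trend put in, over 15161 genes, it called 609 of 14964 unchanged genes before removal of the trend and 1 after. For both checks the simulated counts held counting error only, without spread between replicates. They do not show how many calls such spread gives. Of 200 random lists, 7% fell outside the percentile limits.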

Results

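Polyadenylated RNA of MEL cells, an established line of mouse erythroleukemia cells that stand at the stage of red blood cell precursors, was measured by single-end RNA sequencing. The labels give 1 group of 2 biological replicates, so the data describe the expressed genes of this line and the spread between its replicates, and no condition was compared with another. Replicate 1 held 67735380 and replicate 2 held 79923143 expected counts on genes. A count of 0 allows a share of up to 4.43e-06% of the reads in replicate 1 and 3.75e-06% in replicate 2, which covers counting error only. Values are TPM, the relative number of transcripts of a gene corrected for length, given as mean ± SD of the replicates (n = 2), and gene positions are on the mouse genome build mm10.

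At TPM of at least 1 in both replicates, 11655 of 43346 genes were detected, 10045 of them protein-coding (46.8% of the 21474 protein-coding genes), and 647 were processed pseudogenes, which share much of their sequence with their parent genes. The 10 most abundant genes held 8.88% ± 1.5 (SD, n = 2) of TPM, the top 100 held 30.7% ± 0.918 and the top 1000 held 66.7% ± 0.354. Of expected counts in place of TPM, the shares were 6.36% for the top 10 and 20.3% for the top 100. The protein-coding genes with the highest levels were the translation elongation factor gene Eef1a1 at 10309.7 ± 1905 TPM, the mitochondrial ATP synthase gene mt-Atp8 at 9322 ± 3609 and the ribosomal protein gene Rpl41 at 7226 ± 1474. Seventh among them was the erythroid carbonic anhydrase gene Car1 at 4289 ± 752 TPM, followed by Ptma at 4247 ± 1163 and Npm1 at 4109.9 ± 2383. The mitochondrial chromosome took 4.33% ± 1.10 of TPM, and the cytosolic ribosomal protein genes took 10.9% ± 1.67. Of expected counts they took 2.17% and 4.57%.

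The question of which lineage's genes the line expressed was put to 31 gene lists chosen before the data were examined. Adult globin, heme, iron, erythroid factor and red cell membrane genes had medians above the central 95% of random lists of protein-coding genes, and embryonic globin genes lay inside it. Against random lists of genes with TPM of at least 1, the heme enzymes and erythroid transcription factors lay inside it. The embryonic globin genes then lay below it, since such lists cannot have a median under 1 TPM. The adult alpha globin genes, which encode a chain of hemoglobin, stood at 169.9 ± 116 TPM for Hba-a1 (ENSMUSG00000069919.7; chromosome 11, 32283511-32284465) and 283 ± 63.8 for Hba-a2 (chromosome 11, 32296489-32297298). The beta chain genes stood at 106 ± 52.8 for Hbb-bs (chromosome 7, 103826534-103828096) and 94.6 ± 27.7 for Hbb-bt (chromosome 7, 103812524-103813996). All 4 measured members reached 10 TPM in both replicates, and the list's median of 138 TPM lay at percentile 99.6 of 10000 random lists of protein-coding genes. List medians are taken over the genes' mean TPM, and the medians within replicate 1 and replicate 2 are given beside them. For this list they were 81.4 and 198. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the division of reads within each set of copies is uncertain. At Hbb-bs and, in replicate 2, at Hba-a1 most TPM lay on a retained-intron transcript: Hbb-bs-202 held 94.2% ± 2.82 of the TPM of Hbb-bs (SD, n = 2), and Hba-a1-202 held 5.14% of that of Hba-a1 in replicate 1 and 98.2% in replicate 2. Hbb-bt has only 1 listed transcript, the protein-coding Hbb-bt-201, so its TPM could lie on no other. Of the 6 embryonic and minor globin genes, 1 reached 1 TPM, Hbq1b at 3.38 ± 2.2, and the median TPM was 0.0975, by replicate 0.075 and 0.11 (percentile 28.2). Hbb-y, Hbb-bh1 and Hba-x each had few counts.

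All 9 enzymes of heme synthesis were above 1 TPM in both replicates, with a median TPM of 48.3, by replicate 37.8 and 60.6 (percentile 99.6). Cpox at 329 ± 30.8 and Alad at 244 ± 69.6 TPM were the highest. Alas2, the erythroid form of the first enzyme of the pathway (chromosome X, 150547375-150570638), stood at 48.3 ± 17.5 against 8.56 ± 2.51 for the ubiquitous form Alas1. Of 28 genes of iron and heme handling, 26 were above 10 TPM in both replicates and the median was 48.2, by replicate 42.7 and 54.2 (percentile 100). This list was led by the ferritin genes Fth1 at 1619 ± 152 and Ftl1 at 1239 ± 691. The transferrin receptor gene Tfrc, through which these cells take up iron, stood at 129 ± 68.5 TPM.

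The 30 measured erythroid transcription factor genes were all above 1 TPM, 28 of them above 10, with a median TPM of 36.4, by replicate 33.9 and 41.8 (percentile 100). The highest were Ldb1 at 413 ± 99.5, Gata1 at 269 ± 150.4 (ENSMUSG00000031162.10; chromosome X, 7959260-7978071), Klf1 at 156 ± 59.9 and Lmo2 at 145 ± 9.33 TPM, all encoding members or partners of the complexes that switch on erythroid genes. The lowest was Sox6 at 2.79 ± 0.877. Of 32 erythroid surface, skeleton and cytosol genes, 31 reached 1 TPM and 28 reached 10, with a median of 53.6, by replicate 47.3 and 50.8 (percentile 100). Car1, Prdx2 at 416 ± 138 and Car2 at 262 ± 23.6 led this list. The anion exchanger gene Slc4a1, a major protein of the mature red cell membrane, was lowest at 0.37 ± 0.156, next to Epb42 at 1.56 ± 0.233.

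**Figure D1:**
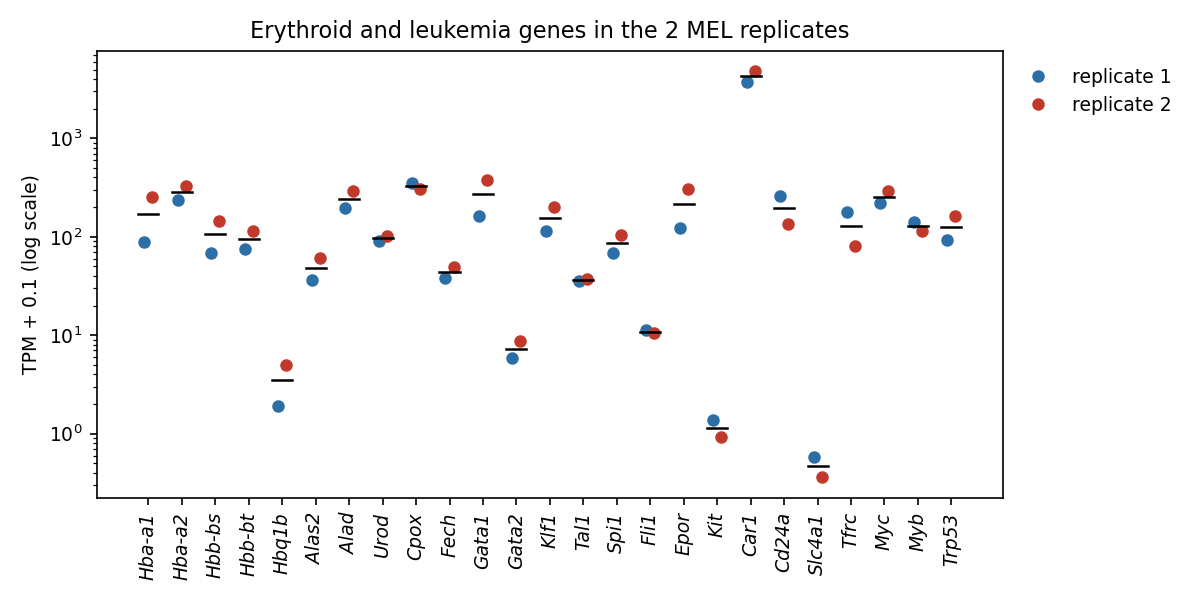
TPM + 0.1 on a log axis of selected erythroid and leukemia genes in replicate 1 (blue) and replicate 2 (red), with their mean as a short line. Gata1, Klf1 and Epor lay above 100 TPM in both replicates, and Slc4a1 lay under 1 TPM in both.

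Set against the markers of other lineages, the 32 erythroid surface, skeleton and cytosol genes were higher than each of 7 lists. The mean of log2(TPM + 1) exceeded that of stem and early progenitor genes by 4.61 (24.4-fold on the TPM + 1 scale), myeloid genes by 4.63 and megakaryocyte genes by 3.53 (11.6-fold). It exceeded that of mast cell and basophil genes by 4.55, B lymphoid genes by 5.03, T and NK lymphoid genes by 5.16 and non-hematopoietic genes by 5.24 (37.8-fold). The difference was positive in both replicates for each of the 7 lists. The two-sided permutation test gave an adjusted p of 1e-05 for each list, the smallest that 100000 permutations can give (Benjamini-Hochberg over 7). The test runs across genes, which are not independent replicates. The lists were not matched on how widely their genes are expressed across cell types, so the p alone does not show lineage identity.

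Some members of the lists of other lineages were nonetheless well above 1 TPM, though such genes need not be confined to those lineages. Of the myeloid genes 10 of 33 reached 1 TPM in both replicates (median 0.04, by replicate 0.02 and 0.06, percentile 15.2), with the integrin gene Itgb2 at 29 ± 8.13, while Irf8 had 0 counts in both replicates. Of the megakaryocyte genes 10 of 22 reached it (median 0.73, by replicate 0.45 and 1.01, percentile 50.4), led by the platelet chemokine gene Pf4 at 168 ± 41, Rap1b at 113 ± 61 and Plek at 79.6 ± 30.3. Stem and early progenitor genes reached it in 5 of 24 cases (median 0.07, by replicate 0.06 and 0.08, percentile 22.8), with Cd48 at 56.3 ± 10.3 and Gata2 at 7.18 ± 2.07. Kit, at 1.05 ± 0.311 (1.27 in replicate 1 and 0.83 in replicate 2), did not reach 1 TPM in both. Mast cell and basophil genes reached it in 5 of 16 (median 0.398, by replicate 0.47 and 0.27, percentile 42), with Il1rl1, the receptor of interleukin-33, at 48.8 ± 21.5. The B lymphoid list had 3 of 19 (median 0.02, by replicate 0.03 and 0.01, percentile 14.8), with the kinase gene Btk at 258 ± 54. The T and NK list had 4 of 24 (median 0.005, by replicate 0.005 and 0.01, percentile 3.6), with Thy1 at 8.19 ± 4.17. The non-hematopoietic list had 4 of 32 (median 0.0075, by replicate 0.005 and 0, percentile 3.55), with Mbp at 27.6 ± 3.22. Posterior mean TPM raised the medians of the stem, myeloid, B, T and NK and non-hematopoietic lists by over 1.5 times, to at most 0.188 (expression of stem and early progenitor genes).

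**Figure D2:**
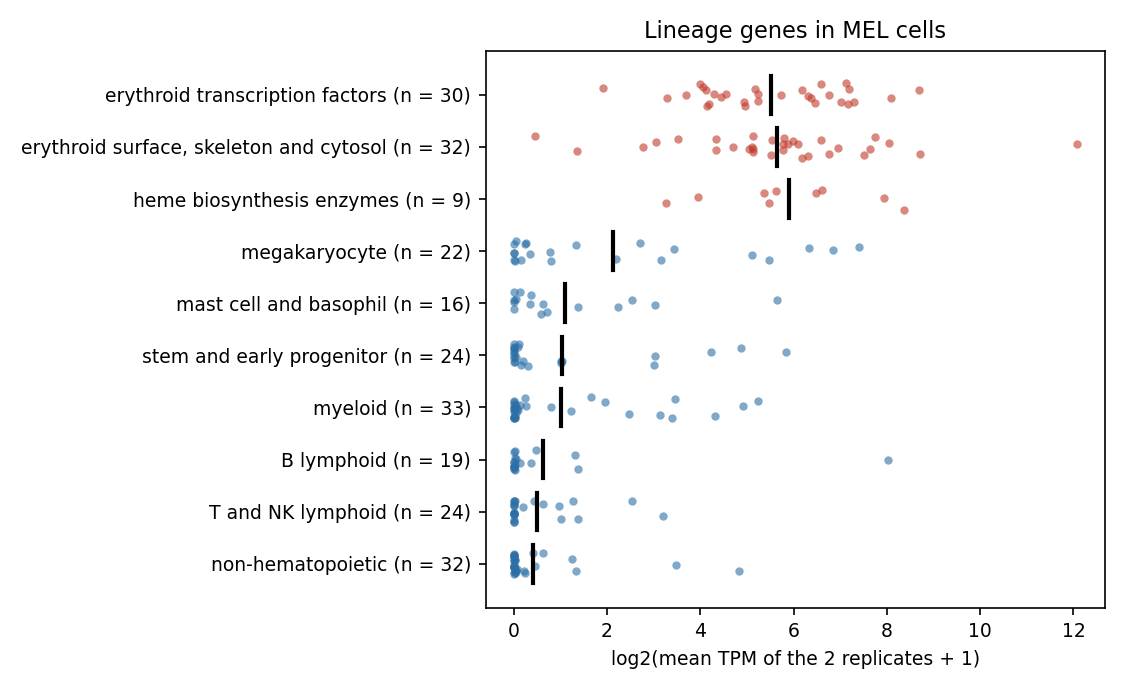
Each point is a gene at log2(mean TPM + 1) on the horizontal axis, grouped by erythroid lists (red) and marker lists of other lineages (blue), and the black line is the mean of each list. The mean is 5.65 for the erythroid surface, skeleton and cytosol list and at most 2.12, for megakaryocyte genes, among the 7 other lineages.

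MEL cells derive from erythroleukemia caused by Friend virus, whose integrations activate Spi1 or Fli1. Spi1, which encodes the transcription factor PU.1 (chromosome 2, 91082390-91115756), stood at 86.1 ± 26.1 TPM and Fli1 at 10.8 ± 0.559, a ratio of 7.73-fold (log2 2.95 ± 0.52). Spib at 0.085 ± 0.0212, Ets1 at 0.12 ± 0.0707 and Erg at 0.075 ± 0.00707 of the same family were low. The erythropoietin receptor gene Epor (chromosome 9, 21958897-21963506) stood at 215 ± 128 TPM. Mst1r, the receptor kinase gene of a Friend virus susceptibility locus, stood at 88 ± 20.2, Nfe2 at 71.4 ± 9.23, Hipk2 at 13.1 ± 3.49 and Fv1 at 5.17 ± 2.4 TPM. Of the TPM of Mst1r, the retained-intron transcripts Mst1r-203 and Mst1r-202 held 56.9% ± 2.56 and 24.9% ± 3.72 (SD, n = 2), and the protein-coding Mst1r-201 stood at 8.57 TPM in replicate 1 and 18.1 in replicate 2. The tumour suppressor genes Cdkn2a and Trp53 stood at 216 ± 74.5 and 126 ± 48.3. In all, 9 of the 13 loci reached 1 TPM, and their median was 13.1, by replicate 15.6 and 10.7 (percentile 92.8). Erythropoietin and cytokine signalling genes reached 1 TPM in 22 of 25 cases, with a median of 25.5, by replicate 28 and 24.5 (percentile 99.9), led by Epor, Grb2 at 206 ± 11.2 and Tfrc.

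Genes of DNA replication and cell division were high. All 45 S phase and replication genes and all 40 mitotic genes were above 10 TPM in both replicates, with medians of 95.1 and 81.2 TPM (percentile 100 for both). By replicate the S phase median was 84.2 and 84.1, and the mitotic median 78.8 and 73.5. Pcna, the sliding clamp of DNA polymerase, stood at 464 ± 76.4, Mcm6 of the replicative helicase at 242 ± 91.7, Top2a at 367 ± 93.5 and Mki67 at 276 ± 99.8 TPM. Of the cell cycle control genes, 22 of 26 reached 1 TPM (median 20.5, by replicate 24.7 and 17.3, percentile 99.8), with Cdk4 at 958 ± 51.1, Ccnd3 at 306 ± 172 and Myc at 256 ± 48.2, and Mycn had 0 counts in both replicates. Of p53 and its targets, 16 of 22 reached it (median 6.14, by replicate 6.76 and 5.81, percentile 85.7), with Mdm2 at 38.4 ± 9.9. Of the apoptosis regulators, 24 of 30 did (median 15.3, by replicate 18.8 and 13.5, percentile 99.3), with the mitophagy receptor gene Bnip3l, which clears mitochondria from maturing red cells, at 213 ± 12.9.

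Glycolytic genes had a median TPM of 415, by replicate 423 and 408 (18 of 19 at 1 TPM, percentile 100), led by Aldoa at 2116 ± 379 and Ldha at 1819 ± 213, while Ldhb had 0 counts. All 23 cholesterol synthesis genes reached 1 TPM (median 23.7, by replicate 24.1 and 25.6, percentile 99.7), led by Fdps at 132 ± 26.3. The 76 measured cytosolic ribosomal protein genes had a median of 1104 (by replicate 963 and 1130.3) and the 13 mitochondrially encoded genes one of 1232, by replicate 1454 and 1404 (percentile 100 for both). With posterior mean TPM the median expression of mitochondrially encoded genes was 2111. DNA methylation and chromatin genes reached 1 TPM in 40 of 42 cases (median 56.2, by replicate 63 and 55.4, percentile 100), led by the maintenance methyltransferase gene Dnmt1 at 461 ± 58.9, with Dnmt3l lowest at 0.01 ± 0.0141. Immediate early and heat shock genes reached it in 22 of 28 (median 22.1, by replicate 16.7 and 23.4, percentile 99.9), with the chaperone gene Hspa8 at 2553 ± 130.4, while Jun had 0 counts. Interferon response genes reached it in 17 of 31 (median 2.8, by replicate 3.13 and 3.02, percentile 75.6), with B2m at 179 ± 7.68, while Zbp1 had 0 counts.

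RNAs without a poly(A) tail were also counted in these polyadenylated libraries. Replication-dependent histone genes reached 1 TPM in 18 of 22 cases (median 3.57, by replicate 2.93 and 3.96, percentile 74.9), with Hist2h3b highest at 50.2 ± 4.57. Other non-polyadenylated RNAs reached it in 7 of 8 (median 32.7, by replicate 44.4 and 26.9, percentile 98.3), led by the ribosomal RNA sequence Gm42418 at 11392 ± 4455 and Rn7sk at 169 ± 17.2. Long noncoding RNAs reached it in 8 of 13 (median 14.4, by replicate 16.1 and 14.7, percentile 94), with the small nucleolar RNA host gene Gas5 at 875 ± 531 and Malat1 at 69.4 ± 58.1. Of the X inactivation and Y-linked genes, 4 of 9 reached it (median 0.03, by replicate 0.04 and 0.03, percentile 27.1): the Y-linked Eif2s3y at 102 ± 75.9, Ddx3y at 38.7 ± 26.5, Uty at 9.36 ± 5.3 and Kdm5d at 4.04 ± 2.1. Xist, the RNA that silences an X chromosome, stood at 0.02 ± 0.0141. Across the 31 lists, 17 medians lay above the central 95% of random lists and 0 below. Against random lists of protein-coding genes that themselves had TPM of at least 1, 9 lay above and 12 below. Adult globin, iron and heme handling and erythroid surface genes stayed above.

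Within 39 measured pairs of related or opposed genes, 19 stood apart: both replicates gave the same sign and the mean log2 ratio was larger than 1.61 (3.06-fold), the 95th percentile of the absolute log2 ratio between replicates. Gata1 exceeded Gata2, the factor it replaces as erythroid cells mature, 34.7-fold (log2 5.12 ± 0.43, SD, n = 2), Klf1 exceeded its antagonist Fli1 13.8-fold (3.78 ± 0.64), and Epor exceeded Kit 173-fold (7.43 ± 1.31). Alas2 exceeded Alas1 5.52-fold (2.46 ± 0.11), Cdk4 exceeded Cdk6 21.5-fold (4.43 ± 0.54), Ezh2 exceeded Ezh1 14.4-fold (3.84 ± 0.87) and the hexokinase gene Hk1 exceeded Hk2 14.4-fold (3.85 ± 0.29). The survival gene Mcl1 exceeded Bcl2l1 10.6-fold (log2 of Bcl2l1 over Mcl1 -3.41 ± 0.36). Ccnd3 exceeded Ccnd2 3.21-fold (1.68 ± 1.02), and without replicate 2 the log2 ratio of 0.96 was inside the replicate spread. Likewise Tet3 exceeded Tet2 3.55-fold (1.83 ± 0.44), with 1.52, also inside it, without replicate 2.

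For the other 20 pairs the difference was not larger than the spread between replicates. In 6 of them the sign changed between replicates. Leaving out 1 replicate took some of them past the limit. Among these were, without replicate 1, Gata1 over Spi1 (1.84) and Ldb1 over Lmo2 (1.81), and without replicate 2 Tfrc over Tfr2 (2.45) and Bcl2l1 over Bcl2 (-1.64). Gata1 over Spi1, whose products block each other, had a log2 ratio of 1.56 ± 0.41 (2.94-fold). Ratios of the same kind were -1.2 ± 0.58 for Tal1 over Lyl1, -1.19 ± 0.64 for Bcl2l1 over Bcl2, 1.51 ± 1.34 for Tfrc over Tfr2, 0.50 ± 0.71 for Fth1 over Ftl1 and -0.05 ± 0.15 for Hmox1 over Hmox2. With 2 replicates the smallest two-sided p of an exact sign-flip test is 0.5, so no p is given for pairs.

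Among 5272 genes with at least 10 TPM in both replicates and more than 1 transcript, 78.4% had the same most abundant transcript in both, and 73.5% ± 0.711 (SD, n = 2) had 1 transcript with the majority of the gene's TPM. Gata1-201 held 96.5% ± 2.04 of Gata1, Tal1-201 held 94.8% ± 5.31 of Tal1 and Pkm-201 held 92.5% ± 1.07 of the pyruvate kinase gene Pkm. At Cdkn2a, Cdkn2a-202 (89274541-89294653 on chromosome 4), which starts at the distal first exon and encodes the p19Arf protein, held 86.4% ± 8.81, and Cdkn2a-201 held 13.6% ± 8.81. Spi1-201 held 68.1% ± 13.1 of Spi1. At Mst1r, the short retained-intron transcript Mst1r-203, with the largest share of TPM, held 15.2% of expected counts, while Mst1r-201, which spans the gene, held 58.4% of counts. TPM divides counts by length, and shares between overlapping transcripts rest on the deposited model.

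Between the replicates of MEL, 7 of 30 gene lists tested lay outside the central 95% of matched random lists. Relative to genes of like expression, higher in replicate 2 were the adult globins, with a median log2 ratio of 0.80 (1.75-fold, percentile 98.8 of matched random lists, 4 of 4 members above 0). Also higher were megakaryocyte genes at 0.67 (percentile 99.3, 12 of 15) and cytosolic ribosomal protein genes at 0.40 (percentile 100, 51 of 76). Lower in replicate 2 were mitotic genes at -0.50 (percentile 0.33, 30 of 40 below 0) and mast cell and basophil genes at -0.80 (percentile 1.08, 7 of 10). Lower too were long noncoding RNAs at -1.26 (percentile 0, 8 of 9) and X inactivation and Y-linked genes at -1.42 (percentile 0.01, 4 of 4). The binomial test of the 2 libraries called 12 mitotic genes, all higher in replicate 1, over all genes tested (12 adjusted over the list alone). It called 2 adult globins higher in replicate 2 (2 adjusted over the list alone). The globins at least 2-fold apart were Hba-a1 and Hbb-bs, with log2 ratios of 1.01 and 1.08. At Hba-a1 the retained-intron Hba-a1-202 went from 4.51 TPM in replicate 1 to 247.5 in replicate 2, and the coding Hba-a1-201 from 83.2 to 4.56. At Hbb-bs the retained-intron Hbb-bs-202 went from 65.9 to 132 and the coding Hbb-bs-201 from 2.63 to 11. As sets of near-identical copies, the 4 globins are not 4 independent genes. The test also called 3 Y-linked genes higher in replicate 1 (3 adjusted over the list alone). The other 23 lists lay inside the central 95%, among them heme biosynthesis enzymes at 0.51 (percentile 95), erythroid transcription factors at 0.28 (percentile 96.3) and S phase genes at 0.01 (percentile 68.2).

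The log2 ratio between replicates moved with the GC content of the transcript: the Spearman correlation across 15161 genes, which are not independent replicates, was 0.765. In the lowest of 10 GC classes of equal size the median log2 ratio was -1.11 (2.16-fold higher in replicate 1), and in the highest it was 0.84 (1.79-fold higher in replicate 2). With this trend removed, a setting chosen after the data were examined, the medians were 0.41 (percentile 99.4) for the adult globins, 0.13 (percentile 100) for ribosomal protein genes, -0.12 (percentile 1.8) for mitotic genes and -0.32 (percentile 0.315) for long noncoding RNAs. Megakaryocyte genes at 0.17 (percentile 94), mast cell and basophil genes at -0.03 (percentile 39.1) and X inactivation and Y-linked genes at -0.11 (percentile 21.7) then lay inside the limits. Mitotic genes also lost their call with the trend removed within 4 classes of expression and with ratios of TPM. Within those classes their median was -0.0887 (percentile 3.44), close to the limit of -0.0953. Long noncoding RNAs lost theirs with GC, length and expression trends removed. Adult globins lost theirs without matching on expression, megakaryocyte genes also with ratios of TPM, and megakaryocyte and mast cell genes with a summed count of at least 200. Ribosomal protein genes kept theirs in each of these settings. The mitochondrially encoded genes, with a median of -0.43 (percentile 12.7) as measured, changed sign to 1.09 (percentile 100).

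**Figure D3:**
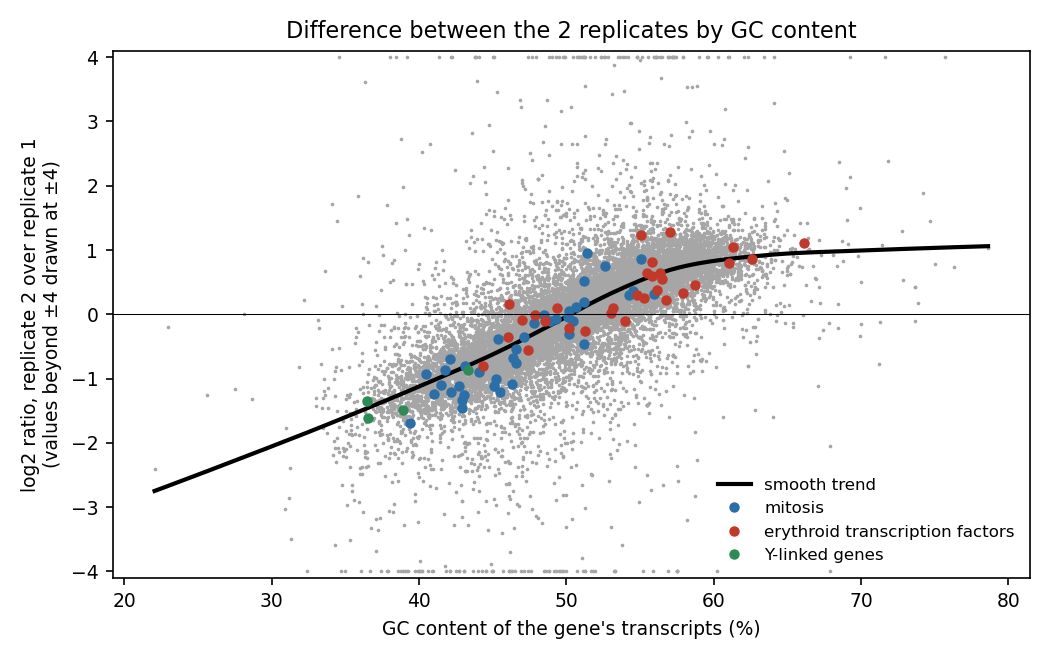
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled expected counts; values beyond 4 in size drawn at the edge) of each tested gene against the GC content of its transcripts in percent, with mitotic genes in blue, erythroid transcription factors in red, Y-linked genes in green and the smooth trend as a black line. The median log2 ratio runs from -1.11 in the lowest of 10 GC classes to 0.84 in the highest.

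Of 15251 genes tested by the exact binomial test, 2974 (19.5%) differed at least 2-fold between the libraries, 1156 higher in replicate 2 and 1818 higher in replicate 1. Scaling by library totals, which moved the median of all genes by 0.12 on the log2 scale, gave 3124 genes and turned the balance to 54.5% higher in replicate 2, against 38.9% with TMM scaling. Among protein-coding genes, Gnat1, the rod transducin gene, was higher in replicate 2 (24.3 and 247 TPM, log2 ratio 3.34), as was the photoreceptor gene Rpgrip1 (1.07 and 26.9 TPM, 4.63). Neither was marked as sharing reads with near-identical copies. The use of strand is not given, so reads from overlapping genes are not excluded for either. Srp54a, a gene of the signal recognition particle with close copies in the genome, had 11241 expected counts in replicate 1 and 0 in replicate 2; its reads are shared with such copies, so the model's division of reads leaves no bound on the fold. Of the 15 genes with the largest excess in replicate 2, 10 were pseudogenes, and of the 15 with the largest excess in replicate 1, 9 were. The test knows counting error only and compares these 2 libraries, not conditions. With the GC trend removed it gave 1142 of 15161; edgeR's exact test gave 150 genes, but its dispersion came from the same 2 libraries and so holds the differences it is set against.

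Across 43346 genes, log2(TPM + 1) of the replicates correlated with a Pearson coefficient of 0.979 and a Spearman coefficient of 0.930, and with 0.923 and 0.922 across the 12325 genes with mean TPM of at least 1. The biological coefficient of variation from edgeR was 0.419, and 0.270 from the median of gene-wise dispersions in DESeq2. Both were estimated with the GC trend left in, whose removal took away 33.2% of the variance of the log2 ratio. They may therefore hold more than biological spread. The median absolute log2 ratio between replicates was 0.59 (1.5-fold) over tested genes, and 0.24 with the GC trend removed.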

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

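Chosen only after the results were seen were the removal of the GC trend, of the length trend, of the GC trend within 4 classes of expression and of the GC, length and expression trends together, the leaving out of genes that share reads, and the GC-corrected test of Y-linked genes against their X-linked homologs. The pooling of 4 erythroid lists below was not among the comparisons chosen before the data were examined. Short features with numeric identifiers, which no comparison used, held 38904 expected counts in replicate 1 and 104952 in replicate 2, above the limit that a count of 0 allows.

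Of 2939 counted genes with a GC value, 2114 (71.9%) no longer differed 2-fold between the replicates once the GC trend was removed, so a difference in GC-dependent recovery between the libraries may account for most of them. Removal of the length trend ended 14.2% of the calls, which argues against length as the source of most. Genes that share reads were 7.63% of the calls, under the share set in advance, and 2.21% of tested genes. That mark was absent from some pseudogenes with large differences, such as Pgam1-ps2 and Rpl9-ps7. A larger part for read assignment is therefore not excluded. The GC-corrected calls still numbered 1142, and 46.1% of these were pseudogenes, against 27.1% protein-coding genes. What made the libraries differ with GC content stays open, since the labels give no batch. The design has 1 group and names no biological difference, and none was tested for this pattern.

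Globin, heme, erythroid factor and erythroid surface genes together were higher in replicate 2, with a median log2 ratio of 0.35 (percentile 99.94, 54 of 75 members above 0). On their own, as measured, only the adult globins lay outside the limits (percentile 98.8). Heme enzymes (percentile 95), erythroid transcription factors (96.3) and erythroid surface genes (86.35) lay inside. So did 2 related lists that were not pooled, iron and heme handling (90) and erythropoietin and cytokine signalling (92.8). With the GC trend removed the median of the 4 lists together was 0.09, at percentile 99.15. This was beyond the bound against GC content, which was set before that test. Without the 4 adult globins it was 0.0705 at percentile 97.3, just inside that bound (a median of 0.0719), so its size changed little. That bound assumed 1 trend for all genes. The correlation with GC content was 0.885 in the upper and 0.660 in the lower part by count. Low counts hold more counting error, which lowers a correlation, so these values do not show whether the trend itself differed. With the trend removed within 4 classes of expression the percentile of the 4 lists together was 87.5 (93.6 with GC, length and expression trends removed). A culture further along erythroid differentiation, in which division slows, might also lower the mitotic genes, whose GC-corrected median of -0.12 lay at percentile 1.8, past its own bound, at 1.86 with the GC, length and expression trends removed and at 3.44 within 4 classes of expression. The GC-corrected S phase genes lay at percentile 58.1 and the erythroid transcription factors at 23.8 with a median of -0.05. Whether the excess of the 4 lists passes the bound depends on the fit and, narrowly, on the 4 globins, sets of near-identical copies. Within 4 classes of expression the median was 0.0485 with the globins and 0.0470 without them. The GC trend and a culture further along differentiation therefore cannot be told apart.

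The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had a median log2 ratio of -1.42, and with the GC trend removed it was -0.11, which is consistent with the GC trend as the source. Loss of the Y chromosome from part of the cells predicted, in advance, log2 ratios at least 0.5 below those of the X-linked homologs Ddx3x, Kdm6a, Kdm5c and Eif2s3x, and as measured this held for 4 of 4 genes (-0.56, -0.67, -0.95 and -0.57, median -0.62). That prediction took no account of GC content, in which the Y-linked genes are poorer than these homologs (36.5% against 41.6% for Ddx3y and Ddx3x), and with the trend removed the differences were -0.08, -0.15, 0.39 and -0.06 (median -0.0688). With 4 genes, this argues against a loss beyond the GC trend under this single fit only. Under it the median log2 ratio of the mitochondrially encoded genes (median GC 37.1%, Y-linked genes 37.7%) moved from -0.43 to 1.09. The curve may thus remove too much at low GC content, and a loss is not excluded.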

How the results depend on the processing

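The removal of the GC, length and combined trends and the leaving out of genes that share reads were chosen after the data were examined. Of the values that answer a comparison, 105 stayed the same and 18 moved. Staying the same meant keeping direction and side of the threshold, staying within the spread or, for counts, within a fixed fold. Genes detected, 11655 in the main setting, were 15738 at TPM of at least 0.1 and 8921 at TPM of at least 5. An expected count of at least 10 gave 14446, and each of these was labelled the same. With a replicate left out, shares of TPM could not move, since either replicate lies within the SD around their mean. The balance of differing genes turned: 38.9% were higher in replicate 2, but 54.5% with library totals and 50.4% with no minimum fold. The cause of each move was not tested except where stated. The 7 differences between erythroid and other lineage genes kept their direction and stayed past the threshold under each alternative. With expected counts the top 10 genes held 6.36%, the top 100 held 20.3% and the top 1000 held 53.9%, and without mitochondrially encoded genes the top 1000 held 65.6%. Random lists from genes with TPM of at least 1 gave 9 lists above and 12 below the limits, since these lists lie higher by construction; posterior mean TPM gave 1 below, and leaving out each replicate gave 0 to 1 below (1 without replicate 1). With mean TPM of at least 1 the Pearson correlation was 0.923. Genes differing between replicates numbered 1901 with a summed count of at least 200 and 1857 among protein-coding genes, both with fewer genes tested, 11773 with no minimum fold, 150 with edgeR's exact test, whose dispersion holds the differences tested, and 1142 with the GC trend removed, 825 of them shared with the 2974. The median gene-wise dispersion of DESeq2 corresponded to a coefficient of variation of 0.270. At TPM of at least 50, 75.6% of genes had 1 transcript with the majority of TPM; with shares of expected counts 84.0% did, and 86.7% had the same top transcript. Of single lists, pairs and transcripts, 607 values stayed the same, 71 moved, 20 gained and 20 lost a call. Leaving out a replicate leaves 1 library and no test between libraries.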

Other observations

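Settings with the GC trend removed were chosen only after the results were seen. The leading transcript of several named genes differed between replicates. Runx1-203 had 0.461% and 52.8% of Runx1, Myb-202 had 1.92% and 54.3% of Myb, and Myc-208 had 0% and 35.1% of Myc. Alas2-202 held 51.8% ± 3.44 of Alas2 and Dnmt3b-206 80.7% ± 2.15 of the de novo methyltransferase gene Dnmt3b.

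Genes called different between the replicates were spread unevenly over gene classes. Of tested protein-coding genes 15.6% were called, of pseudogenes 40.9% and of other types 25.6%; with the GC trend removed these were 2.62%, 32.2% and 18.1%. Largest in replicate 2 was the ribosomal protein pseudogene Rpl17-ps5, with 0 and 1805 expected counts; its reads are shared with near-identical copies. With the GC trend removed, DNA methylation and chromatin genes had a median log2 ratio of -0.20 (percentile 0.03) and other non-polyadenylated RNAs one of -0.96 (percentile 0.06), against -0.07 and -0.46 as measured.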
